A study of Mus musculus with 3 samples.

How the data were processed

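DNase-seq was carried out on embryonic mouse liver at 13.5 days of gestation. In this assay the enzyme DNase I cuts chromatin where it is open, and the sequenced cut sites show promoters, enhancers and other accessible elements. The labels describe 1 group, a strain of mixed C57BL/6N and 129 background with a homozygous globin mutation that deletes HS2 and HS3, and they number 3 biological replicates. Embryonic liver at this age holds mainly red blood cell precursors, with hepatoblasts and other cell types beside them. No library of unaltered liver is analysed here, so no comparison between genotypes was made, and the spread between the 3 replicates is the only measure of error.

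Each replicate had 4 files used here: a shorter and a longer peak list, a list of footprints, and a file of the false discovery rate of the local cut density. Per the deposited notes beside the files, they were made per sample from filtered alignments to mm10 and were not pooled. The aligner, the peak caller and the footprint caller are not given in the sources used here. The peak signal in the lists the authors deposited is the highest cut density in the peak, normalized to read depth. Its values below 2 were whole multiples of a fixed step in each replicate, within 0.02 steps for 100% of them, and the step was 0.0126 in replicate 1, 0.00837 in replicate 2 and 0.00753 in replicate 3. If 1 step is 1 cut after scaling each library to 1 M cuts (1e+06), these steps correspond to depths of 79.4, 119.5 and 132.7 M cuts, but no file used here states the depth. The FDR values the authors deposited are a p-value type of measure per stretch of bases, and every listed stretch had a value below 0.05. A base that is not listed therefore did not pass that limit, which does not mean that it had no cuts. The deposited footprints carry the same FDR threshold, a q-value of 0.01, in every entry, so they cannot be ranked.

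In all 3 replicates 100% of the peaks in the shorter list held a base with an FDR below 0.001, against 66.6% to 70.2% of the peaks in the longer list. The shorter list was used throughout, and the longer list was an alternative. Gene starts came from GENCODE M21 and sequence from GRCm38, the build of the files, and 21911 protein-coding genes were used. Peaks of different replicates were joined into regions where they shared at least 1 bp. A region with a peak in all 3 replicates was called common to all 3. A promoter was called open where a peak lay within 500 bp of any annotated start of the gene. For counts over all 3 replicates a region common to all 3 had to reach that window, so single peaks in 1 replicate can lie just outside it. The promoter signal is that of the strongest such peak, and 0 means that the shorter list held none. Peaks over 1 kb from any annotated start were called distal. Values are given as mean ± SD over the 3 replicates (n = 3) unless stated otherwise.

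The following choices were made before the data were examined. The 23 gene lists were globin genes, erythroid transcription factors, erythroid membrane and effector genes, heme synthesis and transport, blood stem and progenitor cells, megakaryocytes, macrophages, the neutrophil lineage, B lymphoid cells, T and NK cells, hepatoblasts and fetal hepatocytes, adult hepatocyte metabolism, bile duct cells, endothelial cells, mesenchymal and stellate cells, neurons and glia, skeletal and cardiac muscle, germ cells, keratinocytes, pancreas, cell division, ribosomal proteins and olfactory receptors. Of the 297 listed genes besides the olfactory receptors, 1, Ahsp, had no match in the annotation. Open promoters of a list were compared with those of all other protein-coding genes by a two-sided Fisher's exact test, and the p-values were adjusted over the 23 lists by the Benjamini-Hochberg method. Promoters rich in CpG dinucleotides are open in most cell types, so each list was also compared with 10000 random gene sets of its size, drawn from the same 10 deciles of promoter CpG ratio (2000 sets for olfactory receptors). The number of distal regions within 50 kb of the gene start was compared with the same sets by a two-sided permutation test on the median, whose smallest possible p is 0.0002.

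Footprints inside peaks were searched on both strands for 26 motifs written as consensus sequences. The controls were windows of the same width, moved by 100 bp within the peaks and overlapping no footprint. Each motif was tested by a two-sided Fisher's exact test in each replicate, adjusted over motifs and replicates, and was counted only where all 3 replicates passed 0.05 in the same direction. The motif read backwards without complement was the control for base content. The genes named by rule were every measured globin gene, Gata1, Klf1, Tal1, Nfe2, Epor, Alb, Afp, Hnf4a, Spi1, Mpo and Cd3e, and 1 further gene that is not reported here. For each cell type list and each list past the threshold the rule added the 2 members with the highest mean promoter signal relative to the replicate median among those with a peak in all 3 replicates. It also added the first 2 in alphabetical order among those with no promoter peak. The 3 strongest distal peaks, the 8 motifs with the highest mean odds ratio and the 3 with the lowest were given values. Other genes named below were chosen after their values were seen.

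On simulated data with known answers, the overlap counts differed from those of bedtools in 0 of 2000 cases. Of 100 simulated lists planted as 90% open, the Fisher test called 96 and the CpG-matched test 90, and neither called any of 100 lists without an effect. Of 100 lists with high CpG content and no other effect, the Fisher test called 88 and the matched test 1. The test of distal regions called 100 of 100 lists in which each gene was given 2 more regions, and 0 of 100 others. The simulated genes had independent counts, so this does not measure the test for smaller effects or for genes that share regions. Counts of 32-base words in the genome, used to measure how far a sequence occurs in more than 1 copy, differed from a direct string count for 0 of 369 words. The alternatives were the longer list, the upper 50% of each list by signal, other promoter windows and distances, 1 start per gene, 50% reciprocal overlap, equal numbers of peaks, other control windows, distal footprints alone, and leaving out each replicate in turn. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0, matplotlib 3.10.9 and bedtools 2.31.1 were used.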

Results

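Open chromatin was mapped by DNase-seq in the liver of mouse embryos at 13.5 days, in 3 biological replicates of 1 group that the labels describe as carrying a homozygous deletion of HS2 and HS3. These names are known for DNase I hypersensitive sites of the locus control region, a cluster of enhancers upstream of the β-globin genes. The shorter peak list held 28209 peaks in replicate 1, 57314 in replicate 2 and 41319 in replicate 3, a mean of 42281 ± 14576 (SD, n = 3). They covered 6.55, 11.8 and 9.15 Mb of the genome. The depths implied by the signal steps were 79.4, 119.5 and 132.7 M cuts, so the replicate with the most peaks was not the one with the highest implied depth.

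Most peaks of replicate 1 were found again in the others, while replicate 2 held many that were not. A peak of replicate 2 overlapped 91.4% of the replicate 1 peaks, whereas a peak of replicate 1 overlapped 45.3% of the replicate 2 peaks. Replicate 1 has fewer peaks, which limits the second share. Among the 28209 strongest peaks of each replicate these shares were 76.6% and 76.7%, and the highest of any pair was 85.9%. Over the 6 ordered pairs of full lists the share was 74.3% ± 19.5 (SD). It was 0.485% to 1.00% after all counted peaks of a chromosome were shifted together by a random distance (mean over 100 moves in each pair). Joined over the replicates, the peaks made 61155 regions. Of these 24196, or 39.6%, had a peak in all 3 replicates, 12497 in 2 and 24462 in 1, and 19537 of the last were in replicate 2 alone. Peaks of replicate 2 absent from both others had a median signal of 0.569, against 2.74 for those shared with both. Over the 24196 common regions the log2 signal of replicates 1 and 3 had a Pearson correlation of 0.971, that of replicates 2 and 3 of 0.947 and that of replicates 1 and 2 of 0.936. These are correlations across regions, which are not independent replicates.

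The β-globin locus was examined first, since the names HS2 and HS3 point to it, although the labels state only a globin mutation. The adult genes Hbb-bs and Hbb-bt, which code for β-globin chains of adult hemoglobin, had open promoters in all 3 replicates. The promoter signal was 4.23 ± 1.99 at Hbb-bs (chromosome 7, 103826534 to 103828096, minus strand, mm10) and 3.00 ± 1.09 at Hbb-bt (103812524 to 103813996), SD over n = 3. The promoters of Hbb-y and Hbb-bh1, which code for embryonic globin chains, and of Hbb-bh2 held no peak in either list in any replicate. In the 40 kb upstream of the Hbb-y start at 103853216, the shorter list held 0, 3 and 2 peaks in replicates 1, 2 and 3.

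Upstream of Hbb-y 3 positions were in the shorter list of at least 1 replicate. The nearest, 6.07 kb upstream (103859181 to 103859380 in replicate 2), had a signal of 1.99 in replicate 2 and 1.32 in replicate 3, and in replicate 1 it was only in the longer list, with 0.832. The next, 17.7 kb upstream (103870801 to 103871000), had a signal of 2.69 in replicate 2 and 1.14 in replicate 3. The farthest, at 103877201 to 103877320, was in replicate 2 alone, with 1.33. None of the 3 overlaps an annotated gene. A weaker position, 22.8 kb upstream, was in the longer list of replicate 3 alone, with 0.4445, and replicate 2 had bases below the FDR limit close to it. Between the first 2 positions lay 11.4 kb without a shorter-list peak in any replicate (103859381 to 103870800). Within it, 9.56 kb from 103861164 to 103870728, which is 7.95 to 17.5 kb upstream of Hbb-y, held no base that passed the FDR limit of 0.05 in any replicate. Just outside that stretch, but inside the 11.4 kb, replicate 3 had 1 weak peak in the longer list, 7.88 kb upstream, with a footprint over a pair of NF-E2 motifs. Replicate 1 had no shorter-list peak in the whole 40 kb, so its lack of peaks in the stretch carries little weight, and no unaltered library is analysed here to set beside it.

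**Figure D1:**
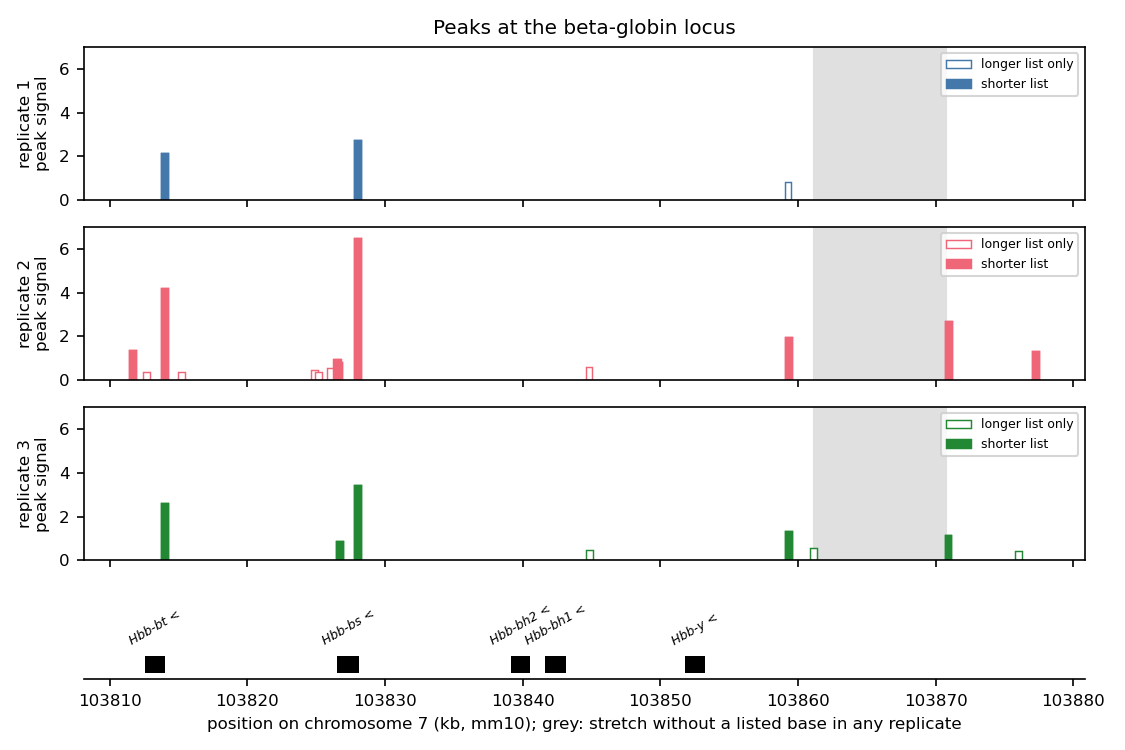
Peak signal in the authors' depth-normalized units (vertical axis) against position on chromosome 7 in kb (mm10) for each replicate, with filled bars for the shorter list, open bars for peaks of the longer list alone, and genes as black boxes. Hbb-bs and Hbb-bt have a bar at their starts in all 3 replicates, and the grey stretch of 9.56 kb was drawn between listed bases, so it holds no bar by construction.

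The α-globin locus, to which the names HS2 and HS3 do not point, served as the comparison within the same libraries. Of 5 known upstream positions, those 8, 21 and 31 kb upstream of Hba-x had a peak in all 3 replicates, the one at 26 kb in replicates 2 and 3, and the one at 12 kb in replicate 2. The strongest peak near 8 kb (chromosome 11, 32267541 to 32267760 in replicate 1) had a signal of 7.52 ± 0.861 and covers the annotated start of Nprl3, the neighbouring gene whose introns house α-globin enhancers. Replicates 2 and 3 also had a peak outside Nprl3, at 32269041 to 32269260 with a signal of 3.63 and at 32269121 to 32269206 with 2.15. The position at 31 kb had a signal of 4.26 ± 1.75 and that at 21 kb 2.87 ± 1.21 (SD, n = 3), and the peaks of both lie within Nprl3. At 26 kb, known as the strongest α-globin enhancer, replicate 2 had a signal of 6.38 and replicate 3 of 2.04. In the longer list replicate 1 had a peak there too, with 2.24.

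At the α-globin genes themselves, Hbq1b and Hbq1a, which code for θ-globin-like chains, had open promoters in all 3 replicates, with signals of 5.27 ± 0.765 and 3.39 ± 0.425. No replicate had a promoter peak in the shorter list at Hba-a2, an adult α-globin gene, or at Hba-x, the embryonic ζ-globin gene. The other adult gene, Hba-a1, had one in replicate 2 alone, with a signal of 1.55 (32283210 to 32283401), and its peak of 2.48 over the end of the gene reaches only the window of another annotated start. Of the 32-base words in the 1 kb around these starts, 12.0% at Hba-a1 and 6.80% at Hba-a2 occur once in the genome, against 100% at Hba-x, so peaks at the adult α-globin promoters are uncertain. The share was 56.3% at Hbq1a, 56.4% at Hbq1b, 79.2% at Hbb-bs and 69.8% at Hbb-bt, so part of the sequence at these open promoters also occurs in other places.

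**Figure D2:**
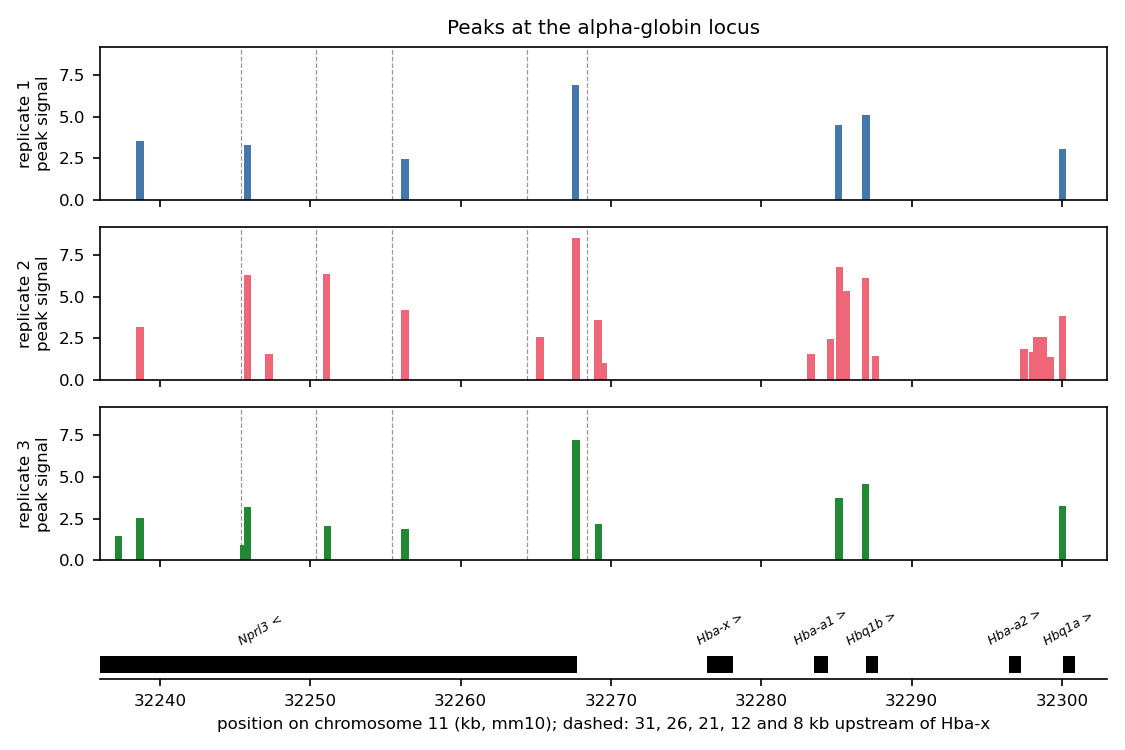
Signal of shorter-list peaks in the authors' depth-normalized units (vertical axis) against position on chromosome 11 in kb (mm10) for each replicate, with genes as black boxes and dashed lines at the 5 known distances upstream of Hba-x. All replicates have bars near the lines at 31, 21 and 8 kb, and only replicate 2 has one near 12 kb.

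Of the 4 red cell lists, 3 had open promoters more often than other genes by the exact test, and the globin list did not (40% open). In CpG-matched sets the median was 10%, and the globin list did not pass against them either (adjusted p = 0.107, permutation). Over all 21911 protein-coding genes 11149, or 50.9%, were open in all 3 replicates. Of the erythroid transcription factors 15 of 16 were open (adjusted p = 0.00136, Fisher's exact test). They included Zbtb7a, a repressor of embryonic and fetal globin genes, with a signal of 17.9 ± 6.44, and Zfpm1, the partner of GATA1, with 15.02 ± 4.11. Nfe2, which codes for a subunit of the activator NF-E2, had 11.6 ± 5.10, Tal1 5.91 ± 0.448, Klf1, an activator of adult β-globin, 2.68 ± 0.469, and Gata1, the master regulator of the lineage, 2.16 ± 0.679 (SD, n = 3). The exception was Gfi1b, with no shorter-list peak in replicate 1, where the longer list had a promoter peak of 1.51.

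Of the erythroid membrane and effector genes 19 of 22 were open in all 3 replicates (adjusted p = 0.00203, exact test). Epb41, which codes for protein 4.1 of the red cell skeleton, had a signal of 19.9 ± 5.41, Bpgm, which makes 2,3-bisphosphoglycerate, 12.5 ± 4.36, and Epor, the erythropoietin receptor gene, 10.03 ± 3.01. Aqp1, Car1 and Hemgn were the exceptions. In the longer list Aqp1 (1.06, 1.46 and 1.34) and Hemgn (1.59, 3.88 and 1.65) had promoter peaks in replicates 1, 2 and 3. Car1 had one in replicate 2 alone in either list, with 0.527. Of the genes for heme synthesis and transport 13 of 15 were open (adjusted p = 0.0144, exact test), with Flvcr1, a heme exporter gene, at 11.2 ± 4.67 and Fech, which inserts iron into heme, at 10.7 ± 1.04. The 2 without a promoter peak were Alas2, the gene of the erythroid first enzyme of heme synthesis, and Slc25a37, that of mitoferrin, of whose promoter words 0% occur once in the genome. In the longer list Alas2 had peaks of 0.778 in replicate 2 and 0.648 in replicate 3.

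All 14 cell division genes (adjusted p = 0.000575, exact test) and all 15 ribosomal protein genes (adjusted p = 0.000397) were open as well. Ccne1, the cyclin E1 gene, had a signal of 18.6 ± 3.92, Top2a, a DNA topoisomerase gene, 13.4 ± 8.07, Rpl3 13.2 ± 3.67 and Rpl10a 12.6 ± 1.22. Against gene sets matched on promoter CpG ratio 3 of these 5 lists stood out, by a permutation test. The erythroid transcription factors were 93.8% open against a median of 50% in the matched sets, and the erythroid membrane and effector genes 86.4% against 45.5% (adjusted p = 0.0023 for each by permutation, from the smallest p these sets allow). The ribosomal protein genes were 100% against 80% (adjusted p = 0.0474, permutation). The heme genes (adjusted p = 0.0753), which also did not pass with 1 start per gene (73.3% open, adjusted p = 0.0511, exact test), and the cell division genes (adjusted p = 0.118) did not pass in that permutation test.

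Few promoters of hepatoblast genes held a peak in all 3 replicates, although these cells share the organ. Of 25 such genes 3 were open, Cebpa, Apoh and Trf (adjusted p = 0.000397, exact test, and 0.0046 against matched sets by permutation). Cebpa, a transcription factor gene that white blood cells also use, had a signal of 2.98 ± 0.386. The regions at Apoh, with 1.67 ± 1.78, and at Trf also reach the start of another gene. Alb and Afp, which code for albumin and α-fetoprotein, had no promoter peak in the shorter list. In the longer list Afp had 0.731 in replicate 1 and 1.19 in replicate 2, and Alb 0.399 in replicate 3. The replicates differed here more than in any other cell type list, with 5, 18 and 7 of the 25 promoters open in replicates 1, 2 and 3. These shares are 20%, 72% and 28%, against 51.4%, 57.5% and 55.5% of all genes in the same replicates. The list thus lay below all genes in replicates 1 and 3 and above them in replicate 2. Hnf4a, a central hepatocyte transcription factor gene, was open in replicate 2 alone, with 0.870. Without replicate 1 the share open in both others was 28% (adjusted p = 0.0272), and without replicate 3 it was 20% (adjusted p = 0.00492, exact tests), against 12% in all 3. In the longer list 40% of the promoters were open and the list no longer passed (adjusted p = 0.191, exact test).

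Other cell types of the organ were lower than the rest of the genes too by the exact test, which does not account for CpG content. No promoter was open in all 3 replicates among 14 endothelial genes, such as Cdh5 and Emcn (adjusted p = 0.000397), among 7 bile duct genes, such as Cftr and Epcam (adjusted p = 0.0144), and among 12 genes of the neutrophil lineage, such as Mpo, Camp and Cebpe (adjusted p = 0.000635, exact tests). Of 16 macrophage genes 1 was open, Hmox1, a heme oxygenase gene, with 2.26 ± 0.248, while Adgre1 and C1qa had no peak (adjusted p = 0.000635, exact test). Of 12 mesenchymal and stellate cell genes Col1a1, with 2.41 ± 0.386, and Reln, with 1.33 ± 0.273, were open, and Acta2 and Col1a2 were not (adjusted p = 0.0276, exact test). Of 16 genes of adult hepatocyte metabolism Ass1, of the urea cycle, was open, with 2.03 ± 0.390, and Arg1 and Cps1 were not (adjusted p = 0.000635, exact test). Against CpG-matched sets the macrophage (6.25% against a median of 12.5%, adjusted p = 0.686), neutrophil (adjusted p = 0.126) and adult hepatocyte lists (adjusted p = 0.526) did not pass, by permutation.

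Among blood lineages, 3 of 14 megakaryocyte genes were open (adjusted p = 0.0413, exact test): Itga2b, an integrin gene of platelets, with 8.59 ± 1.90, Nbeal2, needed for platelet granules, with 8.07 ± 2.20, and Vwf. Gp1bb and Gp6 were not. Of 10 T and NK cell genes Lck, a kinase gene, was open, with 5.37 ± 0.252, and Cd3e and Cd4 were not (adjusted p = 0.0185, exact test). Against CpG-matched sets neither list stood out. The megakaryocyte share was 21.4% against a matched median of 21.4%, and the T and NK share 10% against 20% (adjusted p = 0.592, permutation). Neither passed the exact test with the upper 50% of peaks, nor did the megakaryocyte list with a window of 1000 bp. The 10 B lymphoid genes did not pass (adjusted p = 0.229, exact test), with 3 open: Vpreb1, with 5.71 ± 1.45, whose region also covers the start of Top3b, Pax5, with 2.90 ± 0.473, and Ebf1. Blnk had no peak in the shorter list. The 15 blood stem and progenitor genes did not pass (5 open, adjusted p = 0.222, exact test), with Runx1 at 5.12 ± 1.44, Kit at 3.72 ± 0.287, and no peak at Erg and Fli1. Their share rose from 33.3% to 53.3% without replicate 1, while with the upper 50% of peaks it was 13.3% and the list passed as lower (adjusted p = 0.0449, exact test). Spi1, which codes for PU.1 of the myeloid lineage, had a shorter-list peak in replicate 3 alone, with 1.29. In the longer list it had a promoter peak in all 3 replicates, with 1.01, 0.778 and 1.29. The 10 globin genes, with 4 open, did not pass (adjusted p = 0.542, exact test).

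Few promoters of genes from tissues outside the liver held a peak in all 3 replicates. Open in all 3 replicates were 2 of 12 neuron and glia genes, Gfap with 2.35 ± 0.157 and Grin1 with 1.63 ± 0.306, and 2 of 12 germ cell genes, Gdf9, whose region also covers the start of Uqcrq, and Dazl with 4.40 ± 0.691 (adjusted p = 0.0276 for each list, exact tests). A region common to all 3 reached 2 of 13 muscle genes, Mylpf and Ckm (adjusted p = 0.019, exact test). Their regions also reach the starts of Tbc1d10b and Klc3, and Ckm had no shorter-list promoter peak in replicate 3. Of 8 keratinocyte genes Krt10 was open (adjusted p = 0.0435, exact test). The 8 pancreas genes did not pass (Cela1 and Nkx6-1 open, adjusted p = 0.198, exact test). Among the members with no shorter-list promoter peak in any replicate were Gad1, Neurod1, Acrv1, Ddx4, Acta1, Myf5, Dsg3, Flg, Cpa1 and Gcg. Of 1134 olfactory receptor genes, which are used in the nose, 1 was open, Olfr464, with 0.809 ± 0.150, and the adjusted p was too small to be represented. In all, 14 lists were lower than other genes. Against CpG-matched sets 7 were: hepatoblasts, endothelial cells and olfactory receptors (adjusted p = 0.0046 for each), bile duct, mesenchymal and germ cells (0.0247 for each), and neurons and glia (0.0276), by permutation. Without replicate 1 the megakaryocyte (35.7% open) and T and NK cell lists (30%) did not pass (adjusted p = 0.222 for each), nor did the mesenchymal (25.0%, adjusted p = 0.112) and neuron lists (33.3%, adjusted p = 0.206, exact tests). In the longer list these 4 did not pass either, with adjusted p of 0.442, 0.389, 0.06 and 0.06, nor did the bile duct (0.0595) and germ cell lists (0.0996) with the upper 50% of peaks or the muscle list (0.0681) with a window of 1000 bp, all by exact tests.

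**Figure D3:**
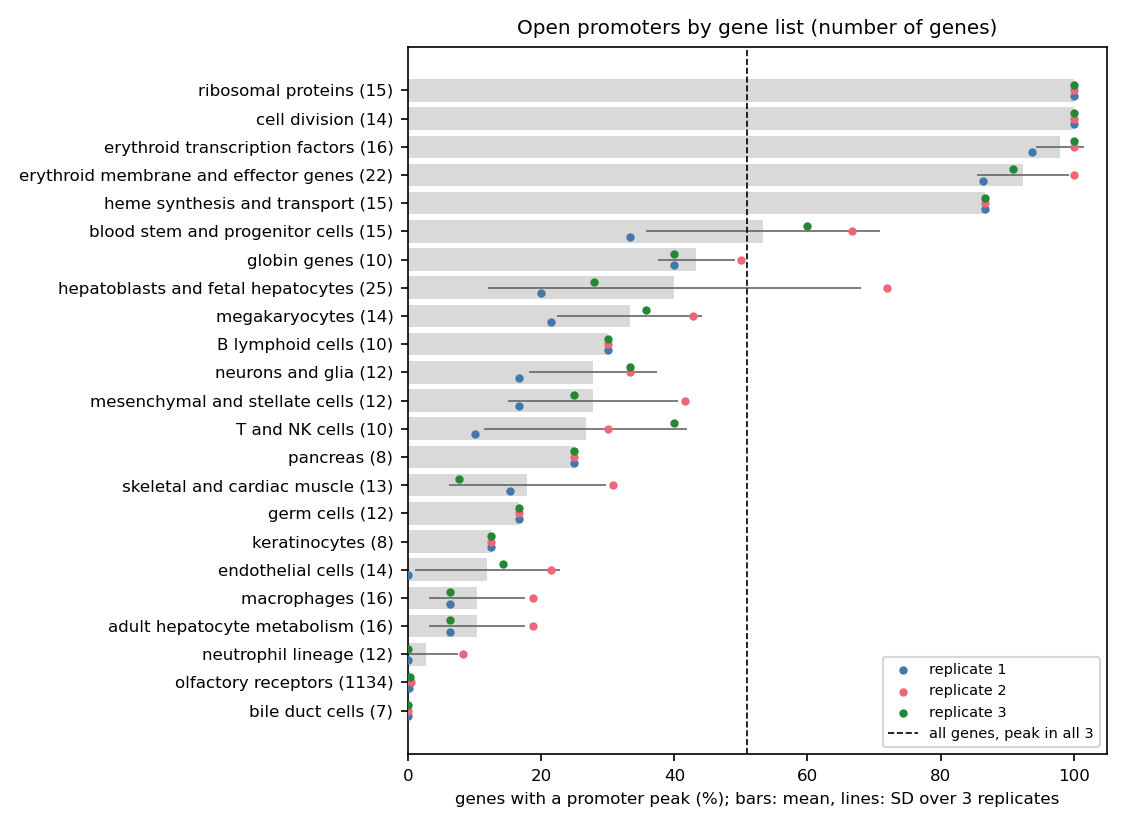
Share of genes with a promoter peak in percent (horizontal axis) for the 23 lists, with grey bars for the mean, lines for the SD over 3 replicates, points for each replicate and a dashed line at 50.9%, the share of all genes open in all 3. The ribosomal, cell division, erythroid and heme lists have means of 86.7% or more, and the hepatoblast list has the widest spread, with replicate 2 at 72.0%.

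Distal open regions were more frequent near the genes of some red cell lists. Of the 24196 common regions 8810, or 36.4%, were over 1 kb from any start. The erythroid transcription factor genes had a median of 3 such regions within 50 kb, against a mean of 0.258 for the medians of matched sets (adjusted p = 0.0046, from the smallest p that these permutations can give). Lyl1, a relative of Tal1, had 8, and Zfpm1 and Gfi1b, which codes for a repressor needed by red cell precursors, had 6 each. The erythroid membrane and effector genes had a median of 1.5 against 0.170 (adjusted p = 0.00767, permutation), with Slc4a1, the anion exchanger gene of the red cell membrane, at 6. It did not pass without replicate 1 (median 2, adjusted p = 0.272, permutation).

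The 10 globin genes had a median of 2 against 0.0682 (adjusted p = 0.00767, permutation). These genes lie in 2 clusters and share their neighbouring regions, so they are not independent. Each of the 5 α-globin genes had 4 or 5 regions and each of the 5 β-globin genes 0. Within 20 kb neither the globin list (median 0.5, adjusted p = 0.0805) nor the erythroid transcription factors (median 1, adjusted p = 0.0621) passed the permutation test. The neutrophil lineage genes had a median of 1.5 against 0.144 (adjusted p = 0.0368, permutation), with Camp and Elane, which code for granule proteins, at 3 each. This result did not pass without replicate 1 (median 2, adjusted p = 0.272, permutation), within 20 kb, within 100 kb or with the upper 50% of peaks. None of the other 19 lists passed, and their adjusted p lay between 0.973 and 1. The medians of the matched sets were close to 0, so the test on the median could not call a list lower. A high p for a list with a median of 0 thus does not show that it matched other genes. The median number was 0 for the genes of heme synthesis and transport (adjusted p = 1, permutation) and for the hepatoblast genes. Taking the mean in place of the median, which was chosen after seeing the data, also called 4 lists higher, with cell division (2.36 against 0.875, adjusted p = 0.0202) in place of the neutrophil lineage, and olfactory receptors lower (0.104 against 0.411, adjusted p = 0.0115, permutation). In the cell division list Aurkb alone had 14 regions and no other member over 4.

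The strongest distal peaks of the data set had high signal in every replicate. The first, at chromosome 9, 123461901 to 123462140, lies inside Lars2, which codes for the mitochondrial leucyl-tRNA synthetase, and had a signal of 90.6 ± 10.4 (SD, n = 3). The next, at chromosome 6, 49236421 to 49236620, lies 7.40 kb from Tra2a and had 71.5 ± 3.96. The last of the 3, at chromosome 3, 5860361 to 5860530, lies 109.2 kb from Gm8797 and had 62.6 ± 3.11. Of their 32-base words 45.9%, 22.5% and 0% occur once in the genome. The reads behind these peaks were not examined.

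Footprints, short protected stretches within open regions, numbered 126616, 194898 and 179791 in replicates 1, 2 and 3, with median widths of 10, 10 and 9 bp. The share inside shorter-list peaks was 71.1%, 75.4% and 70.2%. At 50% reciprocal overlap 34160 footprints of replicate 1, 34546 of replicate 2 and 35058 of replicate 3 were found in both other replicates.

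Motifs of general promoter factors and of CTCF were the most enriched in footprints. The motif of CTCF, an insulator and loop anchor protein, was in 2.81% ± 0.387 of footprints and in 0.0129% of control windows, with a mean odds ratio of 225.7 ± 41.1 (SD, n = 3). Those of NRF1 (31.1 ± 5.27), RFX (12.3 ± 4.75), CREB (12.0 ± 3.54) and SP1 (11 ± 2.50), factors that bind many promoters, followed. Next came the CACCC motif of the KLF family, which includes KLF1 (6.88 ± 1.00), REST, a repressor of neuronal genes (6.50 ± 1.26), and NF-E2, the erythroid activator (5.51 ± 2.21). The adjusted p of NF-E2 was at most 2.24e-09 and that of RFX at most 9.77e-09 in each replicate, by Fisher's exact test. The motif of TAL1 bound together with GATA1, an E-box followed by a GATA site, had 1.84 ± 0.246 (largest adjusted p = 0.0372, exact test). The GATA site alone had 1.01 ± 0.146 and was not called, while with control windows moved by 50 bp it was lower in footprints (0.812, largest adjusted p = 5.94e-05, exact test).

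The lowest mean odds ratios were those of FOXA, a family of liver pioneer factors (0.291 ± 0.0704, largest adjusted p = 4.5e-11, exact test), POU/OCT (0.538 ± 0.121) and HNF1, a liver factor (0.595 ± 0.890), of which only FOXA passed. In all, 13 of 26 motifs were higher in footprints, the remaining ones being YY1, ETS, RUNX and NFY, and 1 lower. Of the motifs read backwards 3 were higher, NRF1 (7.34), CACCC (4.77) and SP1, and 1 lower, and 10 motifs were higher and exceeded their backward form as well. SP1 reads the same backwards in this form, so it has no such control, and RFX and YY1 have no mean ratio to set against theirs, since their backward form was in 0 control windows of at least 1 replicate. The E-box with GATA did not pass with control windows moved by 50 bp (1.40, largest adjusted p = 0.608) or for distal footprints alone (1.83, largest adjusted p = 0.188, exact tests).

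**Figure D4:**
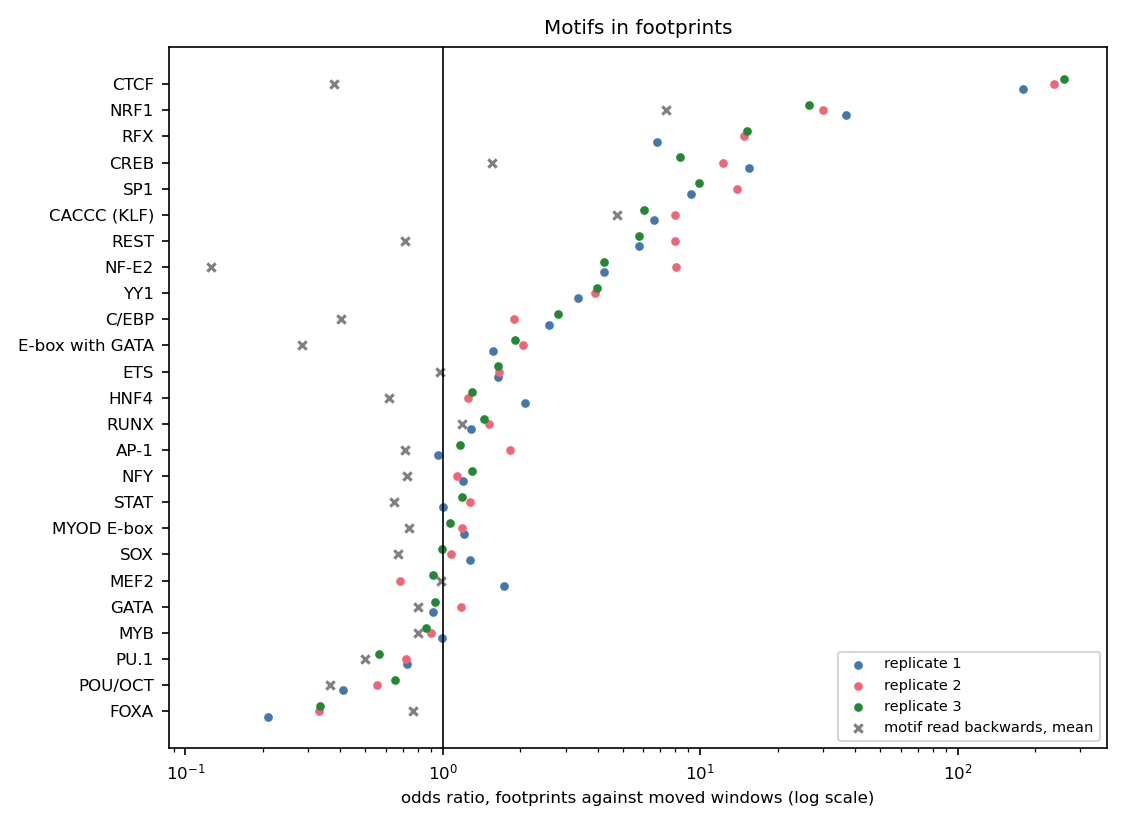
Odds ratio of each motif in footprints against moved windows (horizontal axis, log scale, no unit), with 1 point per replicate and crosses for the mean of the motif read backwards. CTCF lies farthest to the right at a mean of 225.7 and FOXA farthest to the left at 0.291; HNF1, which replicate 1 had in no footprint, is not drawn.

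Peaks near gene starts made up more than any other class. The share within 1 kb of an annotated start was 54.0% ± 10.6 (SD, n = 3), with 64.9% in replicate 1, 43.7% in replicate 2 and 53.5% in replicate 3. Elsewhere in genes lay 25.5% ± 6.62, and between genes 20.4% ± 4.003.

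The labels give no sex for the embryos. Eif2s3y, Uty and Ddx3y, expressed genes of chromosome Y, had open promoters in all 3 replicates, with Eif2s3y at signals of 1.22, 1.33 and 0.919, and Kdm5d had one in replicates 2 and 3. The promoter of Xist, the RNA gene of X inactivation in females, had a peak in replicate 2, with 1.02, and in replicate 3, with 0.723, and none in replicate 1. Chromosome X had 0.416 ± 0.0151 times as many peaks per Mb as the autosomes.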

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

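All tests in this part were chosen after the results they bear on were seen, except the count of hepatoblast promoters in lists of 28209 peaks, which was set down before it was made. The series holds 1 group, so no biological explanation was tested by comparing groups.

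In replicate 3 the longer peak list, which most comparisons leave aside, held a peak 7.88 kb upstream of Hbb-y (chromosome 7, 103861021 to 103861160). Its signal of 0.5425 was higher than that of 29.5% of the peaks in that list, and its lowest FDR was 0.0379. The signal also lay above 3 signal steps (0.0226), but every listed peak reaches that level by the way the step was found. Passing it therefore says nothing about the strength of this peak. One of its 3 footprints, CTCAGCATGACTCAGCATGACTCAGCACTG at 103861077 to 103861106, covers a pair of NF-E2 motifs, an arrangement known from the enhancer core of HS2. Reads shared with another copy are argued against, since 100% of the 32-base words of the site occur once in the genome. A remnant of the element in every embryo and unaltered cells in replicate 3 cannot be told apart here: 21.1% of the 4235 distal replicate 3 peaks of like signal were missing from the longer list of replicate 2 (73.9% for replicate 1), and 0 bases were listed in replicate 3 around the NF-E2 motif 12.8 kb upstream, where a weaker site would fall below the limit. A first remnant test, which scaled the signal to replicate 2 (0.82 against 0.218 for the 5th percentile of its peaks) and would have argued against a remnant, was replaced because it assumes that sites keep their ratios.

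Replicate 2 stood apart from the others, with the most peaks, the most peaks found nowhere else and 18 of 25 hepatoblast promoters open against 5 and 7. Sequencing depth is argued against: in lists of the 28209 strongest peaks the share of distal peaks with a GATA motif was 31.5% in replicate 2, 17.8% in replicate 1 and 23.2% in replicate 3, which is 8.28 percentage points above the higher of the others, and its implied depth was not the highest. A signal stronger alike at every site is argued against too: at matched signal the log2 ratio of replicate 2 to replicate 1 was higher by 0.59 at distal sites with an E-box and GATA motif than at CTCF sites (0.47 ± 0.02 against -0.12 ± 0.01, SE over 361 and 1856 regions), and that to replicate 3 by 0.79, a contrast picked after viewing the ratios by motif. The values in brackets are deviations from the mean log2 ratio of all common distal regions in the same decile of mean signal. A higher share of red cell precursors alone stays open. The test set down beforehand cannot decide it. As that explanation predicted, in lists of 28209 peaks replicate 2 had 4 hepatoblast promoters open against 5 and 4, a difference of -1 from the higher. But this is the whole list of replicate 1, while the cut drops the weaker peaks of replicate 2, whose median signal is 1.06. Weak replicate 2 promoters such as that of Hnf4a (0.870) are lost by the cut itself. Such small counts also do not settle it against the 18 in the full list. In lists of 41319 peaks, tried after that, it had 16 against 7 in replicate 3, 9 more, but this is the whole list of replicate 3, so the count largely repeats the one that prompted it and decides nothing. A better ratio of signal to background in replicate 2 was not tested.

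Among the promoters of red cell genes without a peak in all 3 replicates, those of Hba-a1, Hba-a2 and Slc25a37 consist largely of sequence in more than 1 copy, with 12.0%, 6.80% and 0% of words occurring once. Reads that cannot be placed are a candidate explanation: over all genes the 1004 promoters with under 20% of such words were open at 14.8% of the rate of single-copy promoters in the same CpG deciles (2.99% against 20.1%), although gene families in many copies may also be closed for other reasons, and replicate 2 had a peak with a signal of 1.55 just upstream of Hba-a1. Sequence in many copies can also carry a strong peak: the distal one on chromosome 3, with 0% of words occurring once, had a mean signal of 62.6. The promoter of Alas2 has 100% of its words in a single copy, which argues against shared reads there. Its lack of a peak is instead consistent with the threshold of the shorter list, since the longer list had an Alas2 promoter peak in 2 replicates.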

How the results depend on the processing

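The mean in place of the median was chosen after seeing the data; the other alternatives were chosen before. No result reversed under any alternative that was run. Of 75 alternatives to 15 summary results 61 stayed within the replicate spread or within 1.5 times the main count and 14 moved; of 496 alternatives to 72 results for single lists and motifs 442 stayed on their side of the threshold, 41 lost it and 13 gained it. The longer list gave 63651 peaks per replicate, 9 lower promoter lists and a chromosome X ratio of 0.433, and the upper part of each list by signal, 50% by construction, gave 21140 peaks. Matching on CpG ratio left 3 promoter lists higher and 7 lower. Within 20 kb 1 list had more distal regions, and by the mean 1 had fewer. Footprints shared by all 3 replicates rose to 57875 at an overlap of 1 bp, by construction, and windows moved by 50 bp gave 5 lower motifs. Leaving out each replicate in turn gave 2 to 4 lists with more distal regions (2 without replicate 1), 49720 to 67923 shared footprints, which then had to be shared by fewer replicates, and 1 to 3 lower motifs (3 without replicate 1, 2 without replicate 3). For the counts of lists and motifs the cause was not tested. The test on footprints with the stronger score was not run, since all carry the same value, and YY1 and RFX have no mean odds ratio for distal footprints. Depth limits the weakest sites: a site absent from a list did not pass its threshold at this depth, which does not show that it is closed.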

Other observations

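The tests in this part were chosen after the data were seen. Motifs were also searched in whole distal regions, with control windows that differ from those of the footprints. Among the 8810 distal regions common to all 3 replicates, 4.10% held the E-box with GATA motif of TAL1 and GATA1, against 0.435% of 14482 windows moved by 2 kb (odds ratio 9.78, adjusted p = 1.13e-90, Fisher's exact test). The NF-E2 motif was in 1.79% against 0.214% (odds ratio 8.51), the CACCC motif of the KLF family in 19.7% against 8.97% (2.49) and the GATA site alone in 25.6% against 20.3% (1.36, adjusted p = 7.69e-21, exact test). The CTCF motif was in 21.1% against 0.0621%. Further motifs were more frequent too: the MYOD E-box in 20.3% against 12.5% (1.78), REST (2.29) and PU.1 (1.42), and C/EBP in 10 regions against 0 windows. The motif of HNF4, the hepatocyte factor, was in 1.17% against 1.1% (adjusted p = 0.655, exact test). That of FOXA, which was lower in footprints, was not called here, with 2.91% against 3.16% (odds ratio 0.919, adjusted p = 0.301, exact test). In all, 17 of 26 motifs were more frequent in the distal regions and 2, SOX and MEF2, less frequent. Regions and windows are not independent replicates, and open regions differ from their surroundings in base content, which these windows do not match.

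The gap between replicates was widest, among 9 motifs compared, at distal regions with the E-box and GATA motif. Replicate 2 exceeded replicate 3 there by a median of 0.87 on the log2 scale over 361 regions and replicate 1 by 0.78. At 158 regions with an NF-E2 motif the medians were 0.66 and 0.56, and at 2259 with a GATA site 0.58 and 0.54. Of the motifs of liver factors, FOXA had 0.38 and 0.41 and HNF4 0.22 and 0.28. At 1856 regions with a CTCF motif they were -0.01 and 0.11. These medians are not matched on signal. To match on signal, the mean log2 ratio of all common distal regions in the same decile of mean signal was subtracted. The mean deviations were 0.58 and 0.47 for the E-box with GATA, 0.39 and 0.26 for NF-E2, and 0.33 and 0.25 for GATA. For FOXA they were 0.15 and 0.13, for HNF4 0.05 and 0.04, and for CTCF -0.21 and -0.12. A negative deviation means a ratio below that of the average distal region, not that replicate 2 was weaker there.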
